A study of Mus musculus with 6 samples.

How the data were processed

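Hindlimb buds of E12.5 mouse embryos were compared between 3 wild-type and 3 Pitx1 knockout samples on Illumina bead arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase I, and biotinylated cRNA was prepared with an Ambion MessageAmp kit. The scanner software, background method, normalization and genome build were not given in the sources used here. The deposited value table holds linear intensities, not log values. Of its values 27.9% lie below 0, as after background subtraction. The sorted values of the 6 columns differ by at most 1.09 units with a median spread of 0.046, as quantile normalization would leave them, although no label used here records that step. Array medians were 17.8 to 17.9 units. Such normalization forces arrays to 1 distribution, so a global shift in RNA content would not be seen.

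A second deposited table of non-normalized signals and detection p-values was not used. Its 12 value columns (6 signals and 6 detection p-values) carry running numbers that match no single sample's labels. The background model and the detection filter planned before the data were examined needed those p-values, so the fallback stated in that plan was used. The deposited intensities were corrected with normexp and an offset of 50 (backgroundCorrect in limma 3.58.1, R 4.3.3) and converted to log2, with no further normalization. The offset understates the fold change of dim probes, so mean intensities stand beside the log2 fold changes. Background was taken from the values below 0, whose root mean square was 8.71 units. A probe was called above background at 14.3 units (1.64 times that), and 13715 probes above it on at least 3 of the 6 arrays were tested. No slide or scan date was used.

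Gene names came from GEO's platform annotation, updated through Entrez identifiers to the symbols of assembly GRCm38.p6. Of the 25697 probes, 23978 have 1 symbol, 0 have several and 1719 have none, and 23962 matched by Entrez identifier. No coordinates are given, since the table names no build. Probe sequences were not used, so cross-hybridisation between related genes such as the actins and myosin light chains cannot be excluded. The probe with the highest mean over all 6 arrays stood for a gene, also with an array left out or another setting wherever it was tested, which gave 9535 genes. Of the named genes, 22 have several tested probes. They disagree in sign for 1 gene (Gfra3) and in the call for 3 (Matn4, Myh8 and Tnc).

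Genotypes were compared with limma (lmFit and eBayes, genotype as the only term, knockout minus wild type, two-sided) and Benjamini-Hochberg adjustment over the probes tested, at a threshold of 0.05. Groups of 3 against 3 cannot give a two-sided exact permutation p under 0.1, so no single-gene permutation test was run. Before the data were examined, 21 gene lists with 521 genes were fixed, of which 469 have a named probe. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, both for movement one way and for change in either direction, with adjustment over the 21 lists and without Pitx1. The sex-linked list mixes Xist with Y-linked genes, so its directional tests say nothing about sex. The lists share some genes. Genes were also adjusted over their list alone, which does not cover the 21 lists. The genes named are Pitx1, the 10 genes with the largest fold change in each direction among those past the threshold with no overlap between genotypes, filled to 10 by smallest p, up to 4 genes per list with the smallest p, and 11 genes fixed by name, of which 1 is not reported here. Genes named for any other reason are said to be chosen afterwards.

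The replicate numbers are shared by the genotypes, but the labels give them no meaning as a litter or day. No pair of arrays was identical (Pearson correlations of 0.989 to 0.996). The fit was tested on simulated data with the real probe means and 200 changed probes among 13715, in 20 simulations of knockout against wild type. It recovered 67.3% of probes changed by 0.5 on the log2 scale and 99.5% of those changed by 1, and 4.7% of its calls were false. Shifts of 0.4 in lists of 20 independent probes were called by camera in 100% of cases, and 0.26% of unshifted lists were called. These simulations hold no correlation between genes and give every array the same noise. Their noise was drawn from the variance distribution that limma fitted to these data, so they test the fit under its own model only. The array weights fitted to the real data ran from 0.50 (knockout replicate 3) to 1.58 (wild-type replicate 2), so these rates may not hold here. Alternatives covered the background step, the offset, the normalization between arrays, the filter, a replicate block, the variance model, array weights, the mean over probes and each array left out. Figures were drawn with matplotlib 3.10.9.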

Results

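Gene expression was measured in hindlimb buds of E12.5 mouse embryos, in the strain labelled SV129. The 6 samples fell into 2 genotypes, with 3 samples homozygous for the wild-type Pitx1 allele and 3 samples homozygous for the mutant allele (called knockout here). Total RNA was turned into biotinylated cRNA and hybridised to Illumina bead arrays, 1 array per sample, and each of 25697 probes gave an intensity in arbitrary units, which could lie below 0. Between 13527 and 13553 probes per array lay above the background threshold of 14.3 units. The comparison asked which transcripts depend on Pitx1, a homeodomain transcription factor of the developing hindlimb. The labels do not say whether a sample was 1 embryo or a pool, so p-values refer to differences between samples and not between embryos. In limma, p-values and SEs use variances moderated across probes (9.6 prior degrees of freedom). The number of arrays, 3 per genotype, limits the precision of every value.

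Pitx1 itself was lower in knockout. Its single probe gave 139.6 ± 14.7 units in wild type and 76.5 ± 1.6 in knockout (mean ± SD, n = 3 each), a log2 fold change of -0.51 ± 0.09 (SE; adjusted p = 0.038, limma with Benjamini-Hochberg adjustment). All 3 knockout values, from 75.2 to 78.3, lay below all 3 wild-type values, from 124.5 to 154.0. The knockout signal stayed above background on all 3 arrays. The labels do not give the deleted part of the gene, so this probe does not settle whether the allele is null. The call held at an adjusted p of 0.048 without knockout replicate 1 and was lost when any other single array was left out (adjusted p of 0.063 to 0.30). The fold kept its direction each time, which leaving out 1 array could not change, since the genotypes did not overlap.

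Tbx4, the T-box gene of hindlimb identity, averaged 354.4 ± 48.8 units in wild type and 226.7 ± 18.9 in knockout (SD, n = 3 each). Its log2 fold change of -0.51 ± 0.10 (SE) missed the threshold over all probes (adjusted p = 0.076, limma). The genotypes did not overlap for Tbx4, as for 13.3% of all probes tested, where 10% is expected by chance. Of the 8 hindlimb identity genes tested besides Pitx1, 0 passed over all probes by limma and 3 had an unadjusted p under 0.05. Adjusted over the list alone, Tbx4 fell and Hoxd10 rose. Without knockout replicate 2 the count was 1, namely Isl1, named after its values were seen, whose log2 fold change of -0.65 ± 0.11 (SE, adjusted p = 0.037) was -0.30 with all arrays (adjusted p = 0.75). Hoxd10, a posterior Hox gene, averaged 1979 ± 217 units in wild type and 2476 ± 232 in knockout (log2 fold change 0.31 ± 0.10 SE, adjusted p = 0.42 over all probes). It also belongs to the list of limb Hox genes, and adjusted over that list alone it did not pass (limma adjusted p = 0.088). Hoxc10 (log2 fold change 0.22 ± 0.10 SE, adjusted p = 0.61) and Hoxc11 (-0.01 ± 0.09, adjusted p = 0.97) did not pass. The hindlimb identity list did not move one way (camera adjusted p = 0.76), while the fry test for change in either direction gave an adjusted p of 0.030. By that test no other of the 21 lists passed (adjusted p of 0.072 to 0.96), muscle (0.078) and erythroid genes (0.072) included. This fry test is given for all arrays at the main setting only. Its adjustment does not cover the several tests run per list. Both probes of Tbx5, the forelimb counterpart of Tbx4, lay below background on all 6 arrays. Of the 5 forelimb identity genes tested, 0 passed by limma and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.40).

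Across all 13715 probes tested, 30 passed an adjusted p under 0.05 in limma, of which 21 were lower and 9 were higher in knockout. Of these probes, 12 changed at least 2-fold, and all 12 were lower in knockout. The 27 named probes represented 26 genes, of which 21 fell and 5 rose. An unadjusted p under 0.05 was reached by 1103 probes, where 686 are expected by chance. The count of 30 depended on single arrays. It was 3 without wild-type replicate 1, 4 without wild-type replicate 2 and 0 without wild-type replicate 3. It was 91, 48 and 32 without knockout replicates 1, 2 and 3. Without wild-type replicates 1, 2 and 3, 718, 913 and 710 probes had an unadjusted p under 0.05 in limma, against the 686 expected. Without knockout replicates 1, 2 and 3 the numbers were 1442, 1938 and 683. All 30 probes kept their direction in each of these fits. The genotypes did not overlap for any of the 30, so leaving out 1 array could not reverse a direction. Knockout replicate 3 stood apart from the other arrays. It lay at 22.3 on the first principal component, which held 44.2% of the variance, while the other 5 arrays lay between -8.9 and 1.4.

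**Figure D1:**
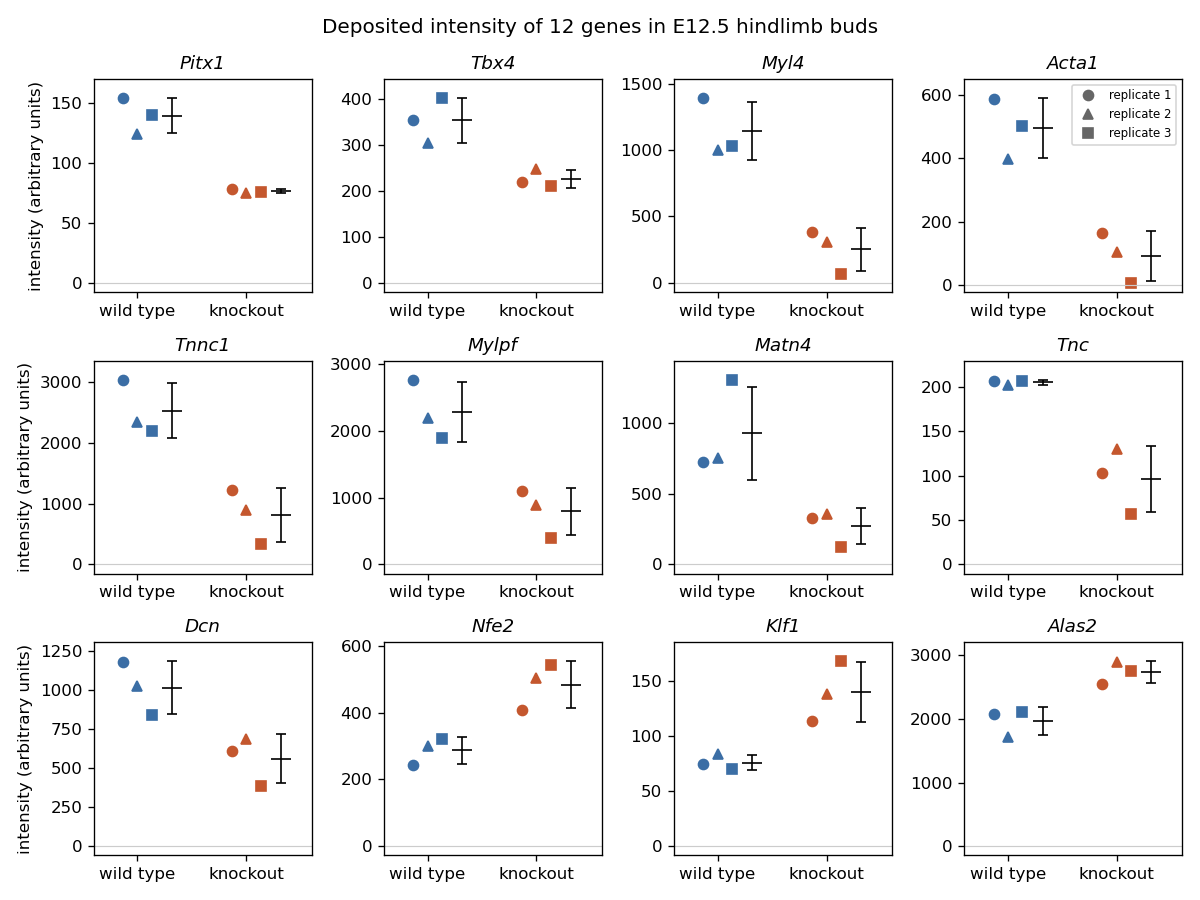
Deposited intensity in arbitrary units (linear axis) of 12 genes in the 3 wild-type and 3 knockout arrays, with a symbol for each replicate and the mean ± SD as a black bar beside each group. Pitx1 lay at 76.5 units in knockout against 139.6 in wild type, the muscle genes Myl4, Acta1, Tnnc1 and Mylpf were lowest in knockout replicate 3, and Nfe2, Klf1 and Alas2 were higher in all 3 knockout arrays.

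Skeletal muscle genes were the largest group among the changes, and all of them were lower in knockout. Of the 27 muscle genes tested, 8 fell, 0 rose and 19 did not pass over all probes. Adjusted over the list alone, 20 fell. Every one of the 27 had a log2 fold change below 0, with a median of -0.54. Myl4, an embryonic myosin light chain, fell from 1142 ± 218 to 252 ± 164 units (SD, n = 3 each; log2 fold change -2.05 ± 0.31 SE, adjusted p = 0.018, limma). Acta1, skeletal alpha-actin, fell from 495.9 ± 93.9 to 92.5 ± 78.6 units (log2 fold change -1.91 ± 0.28 SE, adjusted p = 0.017) and was above background on 2 of the 3 knockout arrays. Tnnc1 and Tnnc2, the slow and fast troponin C genes, fell by 1.68 and by 1.53 on the log2 scale. Mylpf, the fast regulatory myosin light chain, fell by 1.53 on the log2 scale, from 2282 ± 445 to 793 ± 355 units. Myh8, a perinatal myosin heavy chain, fell from 153.5 ± 36.6 to 35.4 ± 13.3 units (log2 fold change -1.06 ± 0.13 SE, adjusted p = 0.0064), while its second probe gave -0.31 and did not pass (adjusted p = 0.40). Chrng, the fetal acetylcholine receptor subunit, fell from 229.2 ± 31.3 to 79.4 ± 40.6 units, and Tnnt1, slow troponin T, named after its values were seen, also fell.

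Among transcription factors of the muscle list, Myog and Mef2c, named after their values were seen, gave log2 fold changes of -0.63 and -0.52. Both fell when adjusted over the list alone and did not pass over all probes (limma adjusted p = 0.12 and 0.32). Myod1, a myogenic factor, averaged 42.7 ± 3.4 units in wild type and 38.1 ± 26.5 in knockout (SD, n = 3 each; log2 fold change -0.09 ± 0.14 SE, adjusted p = 0.89, limma). Actn2 and Sln, which were outside the list but among the 10 largest decreases, encode the Z-disc protein alpha-actinin 2 and the calcium pump regulator sarcolipin. Actn2 fell from 247.4 ± 18.4 to 57.4 ± 28.6 units (log2 fold change -1.32 ± 0.14 SE, adjusted p = 0.0029), and Sln fell by 1.25 on the log2 scale and was above background on 2 of the 3 knockout arrays. As a list, muscle genes lay below other genes by camera with its preset correlation (adjusted p = 4.5e-29). With an estimated correlation of 0.52 between the genes, the call was lost (adjusted p = 0.29). The fry test, which asks whether the list moves one way and not how it compares with other genes, gave an adjusted p of 0.20. The mean log2 level of the list relative to wild type was -0.49, -0.64 and -1.18 in knockout replicates 1, 2 and 3, and the wild-type arrays lay between -0.07 and 0.10. Without knockout replicate 3, 10 muscle genes passed and the list median was -0.43. Without wild-type replicate 1 or 3 none passed, and 19 had an unadjusted p under 0.05 in each case. Without wild-type replicate 2 the count was 1. Without knockout replicate 1 it was 15.

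Few cartilage and connective tissue genes passed, although most had a log2 fold change below 0. Of 21 cartilage genes tested, 1 fell, 0 rose and 20 did not pass, and 18 had a log2 fold change below 0. The gene that fell was Matn4, which encodes the matrix protein matrilin 4, from 926 ± 327 to 270 ± 128 units (SD, n = 3 each; log2 fold change -1.58 ± 0.26 SE, adjusted p = 0.022, limma). Its other 2 probes gave -0.92 (adjusted p = 0.054) and -0.53 (adjusted p = 0.26). Adjusted over the list alone, Matn1 also fell (limma adjusted p = 0.22 over all probes). Sox9, the master regulator of chondrogenesis, gave a log2 fold change of -0.35 ± 0.17 (SE) and Col2a1, the main cartilage collagen, gave -0.30 ± 0.18, and neither passed (adjusted p = 0.62 and 0.69). Of the 23 tendon and connective tissue genes, 1 fell, 0 rose and 22 did not pass, and 5 fell when adjusted over the list alone. Tnc, the matrix glycoprotein tenascin C, fell from 205.6 ± 2.8 to 96.6 ± 37.0 units (log2 fold change -0.74 ± 0.13 SE, adjusted p = 0.038), and its second probe gave -0.72 with an adjusted p of 0.052. Dcn, which encodes decorin, gave -0.80 ± 0.16 (adjusted p = 0.076), and Mkx, a tendon transcription factor, gave -0.52 ± 0.11 (adjusted p = 0.12). Scx, the early tendon marker, gave 0.07 ± 0.11 (adjusted p = 0.89).

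The median log2 fold change was -0.18 for both lists, and camera with its preset correlation gave each an adjusted p of 4.4e-05. With an estimated correlation the calls were lost (adjusted p = 0.42 for cartilage and 0.45 for tendon and connective tissue). Knockout replicate 3 carried the lowest level of both lists, at -0.43 in each, against -0.14 and -0.20 (cartilage) and -0.02 and -0.21 (tendon) in knockout replicates 1 and 2. Wild-type replicates 1, 2 and 3 lay at -0.08, -0.09 and 0.16 for cartilage and at 0.08, -0.07 and -0.01 for tendon. For tendon the genotypes thus overlapped, and for cartilage they did not. Without knockout replicate 3 the medians were -0.11 and -0.10. Without any 1 wild-type array neither Matn4 nor any tendon gene passed over all probes by limma, with 2 to 9 cartilage genes and 4 to 7 tendon genes lower at an unadjusted p under 0.05. The count of tendon genes was 2 without knockout replicate 1 and 3 without knockout replicate 2. Of the 11 joint genes, 0 passed by limma and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.26), and Gdf5, a marker of the joint interzone, gave -0.38 ± 0.14 (adjusted p = 0.51).

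Most erythroid genes had a log2 fold change above 0, although few passed. Of 18 tested, 1 rose, 0 fell and 17 did not pass over all probes, and 11 rose when adjusted over the list alone. A log2 fold change above 0 was seen for 16 of the 18, with a list median of 0.31. Nfe2, an erythroid transcription factor, rose from 287.0 ± 40.9 to 483.9 ± 69.8 units (SD, n = 3 each; log2 fold change 0.63 ± 0.12 SE, adjusted p = 0.046, limma). Klf1, another erythroid transcription factor, averaged 76.0 ± 6.8 and 140.1 ± 27.2 units (log2 fold change 0.51 ± 0.10 SE, adjusted p = 0.076). Alas2, the first enzyme of erythroid heme synthesis, gave 0.46 ± 0.10 (adjusted p = 0.12) and Blvrb, a biliverdin reductase, gave 0.48 ± 0.11 (adjusted p = 0.16). Among the 5 genes that rose over all probes, Pdzk1ip1 reached a log2 fold change of 0.83 ± 0.13 and Car2, a carbonic anhydrase, reached 0.82 ± 0.14. Ctse, which encodes cathepsin E, rose by 0.70 ± 0.11 on the log2 scale, and both probes of the nonagouti gene (symbol a) passed, at 0.72 and 0.54. Among genes higher in knockout, Tspan33, Pkhd1l1, Klf1, Ermap and Ncf4 had the next smallest p-values and did not pass (adjusted p of 0.062 to 0.077).

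As a list, erythroid genes lay above other genes by camera with its preset correlation (adjusted p = 1.0e-12), and the call was lost with an estimated correlation (adjusted p = 0.29). The mean log2 level relative to wild type was 0.19, 0.36 and 0.40 in knockout replicates 1, 2 and 3, and the highest wild-type array lay at 0.05. Without knockout replicate 3 the list median was 0.32. The single call, Nfe2, was lost when any array but knockout replicate 1 was left out, with 10 to 12 of the genes higher at an unadjusted p under 0.05 in limma. Without knockout replicate 1, 4 genes passed.

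**Figure D2:**
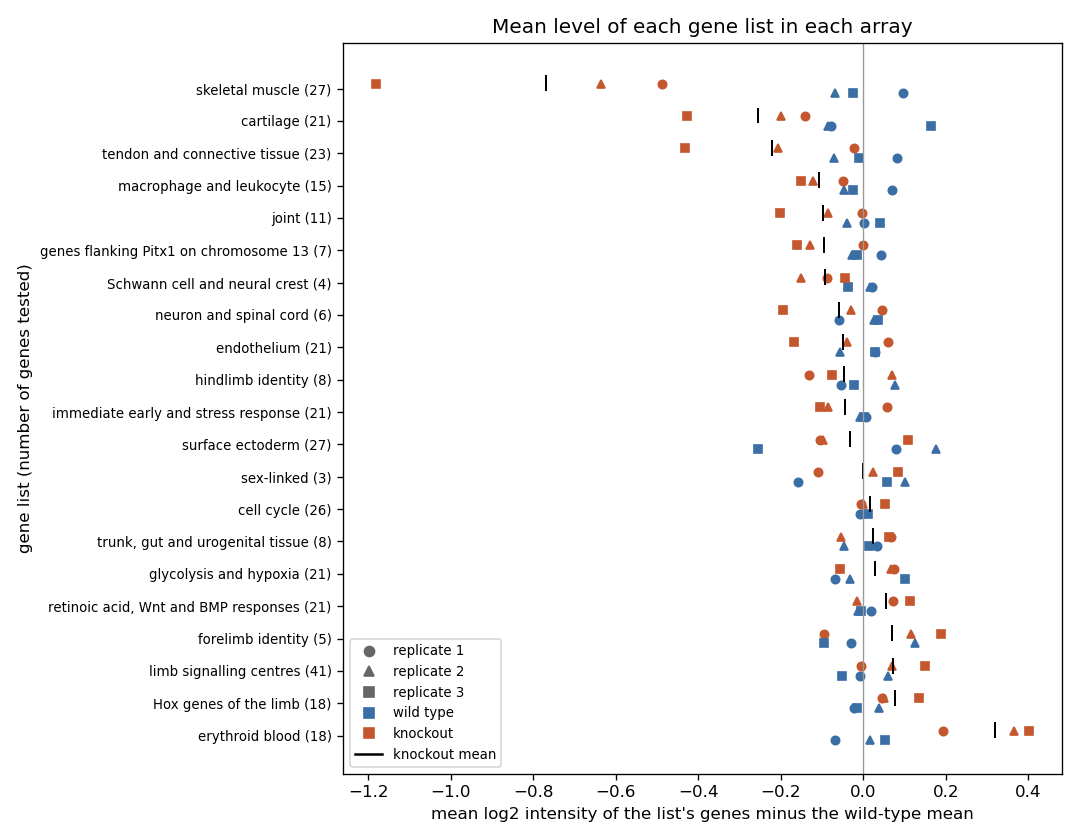
Mean log2 intensity of the tested genes of each of 21 gene lists in each array, relative to the wild-type mean of that list, with a symbol for each replicate and a black line at the knockout mean. Skeletal muscle lay lowest, at -0.49, -0.64 and -1.18 in the knockout arrays, and erythroid blood lay highest, at 0.19, 0.36 and 0.40.

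Markers of other cell types and of patterning gave few calls. Of 41 genes of the limb signalling centres, 0 passed by limma and 5 had an unadjusted p under 0.05. Aldh1a2, a retinoic acid synthesis enzyme, had the smallest p among them (log2 fold change -0.45 ± 0.11 SE, adjusted p = 0.16) and was the single gene to pass when adjusted over that list alone. Irx3 gave 0.39 ± 0.11 (adjusted p = 0.26), Prrx1, a limb mesenchyme transcription factor, gave 0.28 ± 0.10, and Shh, the signal of the posterior limb, averaged 18.1 ± 6.3 units in wild type and 46.5 ± 53.0 in knockout (adjusted p = 0.75), with its second probe below background on all 6 arrays. Of 18 Hox genes, 0 passed and 4 had an unadjusted p under 0.05. Hoxd9 averaged 392.7 ± 29.9 units in wild type and 548.7 ± 61.1 in knockout (SD, n = 3 each; log2 fold change 0.41 ± 0.10 SE, adjusted p = 0.16, limma) and passed when adjusted over the list alone. Neither list shifted by camera (adjusted p = 0.061 for the Hox genes and 0.076 for the signalling centres). Both passed without wild-type replicate 2 (0.024 and 0.015) and without knockout replicate 1 (0.047 and 0.012). These calls were lost with an estimated correlation (adjusted p = 0.38 for both lists without wild-type replicate 2, and 0.40 and 0.41 without knockout replicate 1).

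The macrophage and leukocyte list lay lower by camera (15 genes, median -0.09, adjusted p = 0.037) and lost the call with an estimated correlation (adjusted p = 0.42). The call was also lost without wild-type replicate 1 (adjusted p = 0.23) and without knockout replicate 2 (0.16). None of its genes passed by limma and 3 had an unadjusted p under 0.05. Its lowest p belonged to Fcgr3, an Fc receptor, with a log2 fold change of -0.29 ± 0.09 (SE, adjusted p = 0.35). Endothelial genes (21 tested, median -0.02, camera adjusted p = 0.37) and surface ectoderm genes (27 tested, median 0.00, adjusted p = 0.73) did not shift with all arrays. The ectoderm list depended on single arrays, with a median of -0.11 and a camera adjusted p of 9.6e-05 without wild-type replicate 3, and of -0.11 and 0.014 without knockout replicate 3. Both calls were lost with an estimated correlation (adjusted p = 0.52 and 0.69). Endothelium reached a camera adjusted p of 0.032 without knockout replicate 1, which was lost with an estimated correlation (adjusted p = 0.42). Camera gave adjusted p-values of 0.33 for Schwann cell and neural crest genes, 0.40 for neuron and spinal cord genes and 0.75 for trunk, gut and urogenital genes. It gave 0.73 for cell cycle genes, 0.52 for glycolysis and hypoxia genes, 0.40 for immediate early and stress genes and 0.25 for retinoic acid, Wnt and BMP response genes. The 7 tested genes of the list flanking Pitx1 on chromosome 13 had a median of -0.08 (camera adjusted p = 0.40), with Cxcl14 at -0.31 ± 0.14 and Tgfbi at -0.35 ± 0.22. The list members Camlg and Sec24a had no position assigned there, so not all of the list is shown to flank Pitx1. In these endothelial to BMP lists, 0 genes passed over all probes by limma, and 2 endothelial, 3 ectodermal, 1 Schwann, 0 neuronal, 0 trunk, 5 cell cycle, 0 glycolysis, 2 immediate early and 5 retinoic acid, Wnt and BMP genes had an unadjusted p under 0.05. Among the flanking genes 0 passed, and 1 had an unadjusted p under 0.05. Adjusted over each list alone, the endothelial gene Aplnr (log2 fold change -0.39), the Schwann list's Ngfr (-0.31) and Aldh1a2 fell. Over all probes none of these passed (limma adjusted p = 0.22, 0.33 and 0.16). Of the 3 sex-linked genes, Xist and the Y-linked Uty and Eif2s3y, 0 passed by limma and 0 had an unadjusted p under 0.05.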

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

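Alternatives were listed before the data were examined, except the offset of 16 and the setting of values below 0 to 0, which were chosen after seeing them. The 30 probes past the threshold, 9 higher and 21 lower, kept their direction in every setting that tested them as probes, but their number did not hold. Their genotypes did not overlap, so leaving out 1 array could not have reversed a direction. With no background step and a floor of 1 it was 0 in limma (0 higher, 0 lower, 0 with at least 2-fold change), with 852 probes at an unadjusted p under 0.05. With an offset of 16 it was 8 (0 higher, 8 lower, 4 at least 2-fold). The Pitx1 log2 fold change became -0.86 (adjusted p = 0.38) and -0.63 (adjusted p = 0.074) under these settings, against 0.022 to 0.38 over its 18 alternatives. An adjusted p under 0.10 gave 53 probes, under 0.01 gave 3, and a tested minimum fold of 1.2 gave 1. The trend and robust variance model called 34 probes, of which 21 were among the 30, with 14 higher and 4 at least 2-fold. Setting values below 0 to 0 kept 27 of the 30, and the mean over probes gave 4 higher genes. Leaving out each array in turn gave 0 to 91 probes, 0 to 35 higher, 0 to 56 lower and 0 to 24 at least 2-fold, with Pitx1 at -0.56 to -0.46. The cause of these changes was not tested. Further quantile or median scaling moved no log2 value by more than 0.0031, so it says nothing about stability. With the replicate block 84 probes passed, 30 higher and 54 lower, including all 30. Deviations of same-numbered arrays correlated at 0.23, 0.17 and -0.07, and not every array correlated best with its own number, so the numbers were not taken as pairs. The muscle and erythroid lists passed under 18 of 20 alternatives, with medians of -1.21 to -0.43 and of 0.27 to 0.47 and adjusted p-values up to 0.29. The cartilage and tendon lists also passed under 18 of 20, with adjusted p-values up to 0.42 and 0.48, and the macrophage list under 14. For these first 4 lists the calls against other genes were lost with the estimated correlation, and fry, which tests a list against no change, did not pass either. The passes of these lists and of the macrophage list all used camera at the preset correlation. Their counts therefore repeat the same test and do not measure its robustness. The trend and robust variance model left the camera adjusted p-values of the muscle and erythroid lists unchanged. The Hox and signalling centre lists passed under 4 and 3 of 20, the replicate block among them, each at the preset correlation. No gene or list past the threshold in either fit changed direction. A slide block was not run, since no slides were used, neqc was not run, and the detection filters were replaced by intensity limits.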

Other observations

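The tests of knockout replicate 3 alone and of more blood were chosen after the results they measure were seen. The values that decide the other tests had not been seen when those were written, but the leading genes of a first fit had, so the set of 22 differentiated muscle genes was drawn with several of its members known to be lower. Genes outside the naming rule were chosen here after their values were seen. Among the 21 genes that fell, Csrp3 (muscle LIM protein) fell by 0.92 on the log2 scale and Atp2a1 (the fast muscle calcium pump) from 407.6 ± 65.1 to 184.3 ± 71.4. Srpk3 fell by 0.66 on the log2 scale and Mustn1 by 0.64. Decreases outside muscle included Rprm, from 1418 ± 231 to 670 ± 94 units, Cbln1 (a secreted cerebellin), from 1604 ± 111 to 958 ± 71, and Ifit3 (an interferon-induced gene), from 155.7 ± 34.0 to 61.5 ± 12.7. Mip, a lens aquaporin, fell from 60.1 ± 9.7 to 8.9 ± 13.4 and was above background on 1 of the 3 knockout arrays. Rprm and Cbln1 had limma adjusted p-values of 0.0064 and 0.011. The 3 unnamed probes past the threshold were all higher in knockout.

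The Xist probe with the higher mean read 46.5, 56.6 and 65.0 units in wild-type replicates 1, 2 and 3 and 81.6, 11 and 149.1 in knockout replicates 1, 2 and 3. The Y-linked Eif2s3y read -5.4, 34.4 and 18.4 in wild type and -6.1, 76.1 and -7.7 in knockout. The second Xist probe read 81.4, 1.5 and 114.8 in knockout replicates 1, 2 and 3. Xist was thus lowest and Eif2s3y highest in knockout replicate 2, with the reverse in replicates 1 and 3. These opposite readings point to a different sex make-up among the knockout samples. Uty, also Y-linked, did not show this contrast and read 31.2 to 48.3 units over the 6 arrays. Eif2s3y also differed within wild type, below background in replicate 1 and above it in replicates 2 and 3, while Xist was above background in all 3. The labels give no sex, and its effect on the comparison was not tested.

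The count of 30 probes was compared with the other splits of the 6 arrays into 3 and 3. The real split gave 30, the highest of the other 9 gave 1, and 1 of the 10 splits gave as many as the real one. With 10 splits the share cannot fall under 0.05.

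The first pattern weighed was that muscle genes were lower in knockout, 8 of 27 past the threshold, with the list call lost at an estimated correlation (adjusted p = 0.29). Without knockout replicate 3 the median of the 22 differentiated muscle genes was -0.46, against -0.59 with it, and all 8 called genes kept an unadjusted p under 0.05, which argues against that array as the whole cause. The medians of the tendon, cartilage, endothelium and ectoderm lists all lay above that of these genes by more than 0.2. They also lay above the upper quartile of these genes (4 of 4 lists). This argues against a dilution that lowers all limb tissues alike. A changed share of muscle among the tissues of the sample would also leave the other lists higher, so this test cannot speak to it. The muscle list fixed before the data were examined had a similar median of -0.54. Whether muscle cells of every stage were fewer stays open. The progenitor median of -0.15 met the bound written against it, but it rests on Eya1 and Eya2 alone. These genes read 35.8 and 61.9 units in wild type, where the offset understates a fold change. The need for at least 3 measured genes was set after that median was seen. A later onset of muscle differentiation without Pitx1 may also account for the pattern, and the genotype is its untested biological explanation.

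The second pattern was that most erythroid genes had a higher mean in knockout, although 17 of 18 did not pass and the list call was lost with an estimated correlation (adjusted p = 0.29). Of those measured, 88.9% had a log2 fold change above 0, consistent with more blood in the knockout buds at dissection, an explanation drawn from these same values. Hba-a1, the most abundant member at 57724 units in wild type near the top of the scale, gave -0.06. Without knockout replicate 3 the median was 0.32, which argues against that array alone. An effect of the genotype on blood content or on blood cell maturation was not tested.

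The third pattern was that both shifts occurred together, as they might if the knockout embryos were younger. The cell cycle list, which a younger bud could show higher, had a median of 0.025, between both bounds set for it, and -0.01 without knockout replicate 3. The early embryonic globins Hba-x and Hbb-bh1 exceeded the adult globins by 0.32 more in knockout than in wild type on the log2 scale (exact permutation p = 0.2, where 0.1 is the smallest the design allows), and the genotypes overlapped. This difference measures little, since Hba-a1 lies near the top of the scale and Hbb-bt averaged below the background limit in wild type. Neither test decides, and stage and genotype cannot be told apart without a staging measure per embryo.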
